A study of Mus musculus with 6 samples.

How the data were processed

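Cells of mouse embryos and adult bone marrow were profiled with droplet-based 3-prime single-cell RNA sequencing (10x Genomics), per the labels' protocols. The deposited values analysed here are UMI counts per gene and barcode, in 1 matrix of 31054 features and 39048 barcodes. The matrix was written by Cell Ranger 3.0.1, per the file headers, whereas the submitters' processing notes name Cell Ranger 2.1.1 and the mm10 build. Whether reads were subsampled to even out depth between libraries is not given in the sources used here. A tdTomato sequence is among the features.

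The 6 samples of the labels fall into 3 groups of 2. Barcodes carry a number from 1 to 4 that matches no sample label, so cells could not be assigned to samples, and the matrix was treated as 1 pooled sample of 4 unnamed libraries. The name of the deposited matrix holds the names of the 2 embryonic driver lines and not that of bone marrow, but names of that kind were not used to assign samples, nor were the values, so whether adult cells are present was not decided here. The tests planned before the data were examined, between embryos of the 2 driver lines and between embryos and adult bone marrow, were therefore not run. What the barcode numbers allow was done instead: values per cell class, with each library's value or the range.

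Barcodes with under 1000 UMIs, under 500 genes or over 10% mitochondrial UMIs were removed, 4461 in all, of which 2756 had too few UMIs and 2051 too many mitochondrial UMIs. Doublets were called per library with Scrublet in scanpy 1.11.5. It marked 4, 0, 199 and 1 cells, and in libraries 1, 2 and 4 this is too few for the caller to have worked, so most doublets probably stayed in those libraries. The 204 marked cells were removed as planned. The kept 34383 cells held 547194376 UMIs.

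Genes were split before clustering. The 113 genes of 11 readout lists and tdTomato were held out, the markers of 22 cell types were used, and a seeded coin toss placed the others, leaving 15563 genes open to clustering and 15491 held out. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were reduced to 30 principal components, and a graph of 15 neighbours was clustered with the Leiden algorithm at resolution 0.6 (python-igraph 0.11.9, scikit-learn 1.9.0), with no correction between libraries. The markers were fixed in the plan, but the rule that turns them into names was set afterwards. A cluster could take a type's name when at least 3 of its markers, and no fewer than the rest of them, were at least 2-fold higher than in all other cells. It stayed unnamed when another type had more markers among its 10 top genes, when several types qualified with none leading, or when its median depth was below that of its libraries divided by 3.

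Counts were summed per class, and per class and library, and divided by the total to give CPM, with exact Poisson 95% intervals. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals, and a share of 0 is given with the upper limit that 3 counts allow. Differences between classes were taken as log2(CPM + 10), which understates differences of low genes, so folds given as CPM pairs are larger for them. List medians cover members with at least 100 UMIs. Their percentiles come from 10000 random lists of held-out genes matched on expression. Shares of cells with a UMI were computed after each cell was thinned to 2000 UMIs, leaving out shallower cells.

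The text names the members of the 2 osteoclast lists, the 4 most abundant members of each other list with any of at least 50 CPM that differed at least 4-fold between macrophage-like and monocyte-like cells, and the 10 highest and 10 lowest held-out genes of a comparison with at least 50 CPM and the same direction in every library with at least 100 cells of both classes (at least 30 for the small osteoclast gene-rich cluster). Ribosomal, mitochondrial and predicted genes were left out of the last part. This rule was fixed beforehand for macrophage-like cells against monocyte-like and progenitor-like cells, and the list members are given mainly for the first of these. Of the other comparisons only some genes are given. The choices of that cluster and of its comparisons, and of the comparisons of single clusters, came after the data were seen.

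Log2 differences were tested on simulated data with 200 genes changed by known folds, drawn at the depths of the macrophage-like and monocyte-like sums over 2764 genes. Of the genes changed 4-fold upward, 100% came back within 0.5 of the true log2 value, and of those changed 4-fold downward 88%. The rates were the same at the depth of the osteoclast gene-rich cluster. The simulated genes had at least 50 CPM in macrophage-like cells, and their counts carried Poisson error only. Lower genes, Tnfrsf11a (41.8 CPM) among them, and spread between cells or libraries were not covered. Clustering of 3040 simulated cells recovered all 40 cells of the small simulated class. Those cells were drawn from 4 fixed class profiles, that of the osteoclast gene-rich cluster among them. They held no doublets and no differences between libraries, so separation among the real cells was not tested by this. Gene positions were looked up by Ensembl gene ID, and 187 of 188 IDs matched. Alternatives covered clustering resolution, doublets, cell filters, genes used, centring within libraries, thinning, pseudocount, a filter on low genes, weights and leaving out each library in turn. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.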

Results

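Single-cell RNA sequencing was used in this series to characterise the precursors of osteoclasts, the bone-resorbing cells of the macrophage lineage, in mouse embryos. The labels describe 6 samples in 3 groups of 2. One group came from Cx3cr1CreER; R26tdTomato embryos given 4-hydroxytamoxifen at embryonic day 9.5, and another from Csf1r-Mer-iCre-Mer embryos given it at day 8.5. Both embryonic groups were collected at E14.5 as macrophage and monocyte lineage cells, and the last group was total bone marrow of mice aged 2 months. In these mice the drug activates Cre in cells using the Cx3cr1 or Csf1r promoter, and those cells and their descendants then carry the red reporter tdTomato. The matrix analysed here held 39048 barcodes from 4 libraries, told apart only by a number at the end of each barcode. Those numbers match no sample label, and which of the 6 samples the matrix holds, adult bone marrow included, is not known from the labels. The libraries are therefore called libraries 1 to 4, are given one by one, and were not compared as sample groups. The libraries held 127153052, 106500620, 129007371 and 198754246 unique molecular identifiers (UMIs), and 8365, 7063, 6997 and 11958 cells were kept, with median depths of 13157, 13077, 14791 and 14154 UMIs per cell. Cells of the pooled matrix were treated as 1 sample, so differences between cell classes were not tested with the libraries as replicates. Intervals below cover counting error only, and ranges are the lowest and highest library.

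Macrophage-like cells, which carry Lyve1, Mrc1, Pf4 and Ms4a7, made up the largest named class, with 9976 of 34383 kept cells, or 29.0% (exact binomial 95% interval 28.5 to 29.5). Monocyte-like cells made up 9.17%, Kupffer cell-like cells, the macrophages of the liver, 4.70%, and microglia-like cells, the macrophages of the brain, 4.06%. Mast cell or basophil-like (4.32%), mesenchymal cell-like (4.04%), erythroid cell-like (2.63%), granulocyte-monocyte progenitor-like (2.33%), neutrophil-like (2.25%), hepatocyte-like (1.35%) and endothelial cell-like (1.09%) cells were also present, with 758 neural cell-like cells. Below, mesenchymal, erythroid, endothelial and neural cells are short for these classes. Doublets among part of the neural cell-like cells were not excluded, as described further on. B cell-like and megakaryocyte-like cells made up 0.468% and 0.125%. The cells were clustered into 24 clusters without the osteoclast genes and other genes read out below.

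Several clusters stayed without a cell type name. Cluster 2, led by Ifitm1, Cd34 and the monocyte chemokine receptor Ccr2, held 1209, 1037, 907 and 1473 cells of libraries 1 to 4. Cluster 4, led by Clec4a1, Clec4a3 and Socs3, held 862, 833, 416 and 577. Cluster 13, led by Trbc2 and Flt3, was found almost only in libraries 3 and 4, with 443 and 588 cells against 7 and 8. Cluster 18, led by MHC class II genes with Cd7 and Cd209a, held 723 cells, and cluster 6, with globin genes and a median of 1736 UMIs, held 1823 cells, of which 1557 were in library 4. Of the named clusters, macrophage-like cluster 11 was led by stress and chemokine genes such as Cxcl2, Cxcl1 and Gadd45b, and monocyte-like cluster 5 by interferon-induced genes such as Ifit3, Isg15 and Rsad2.

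**Figure D1:**
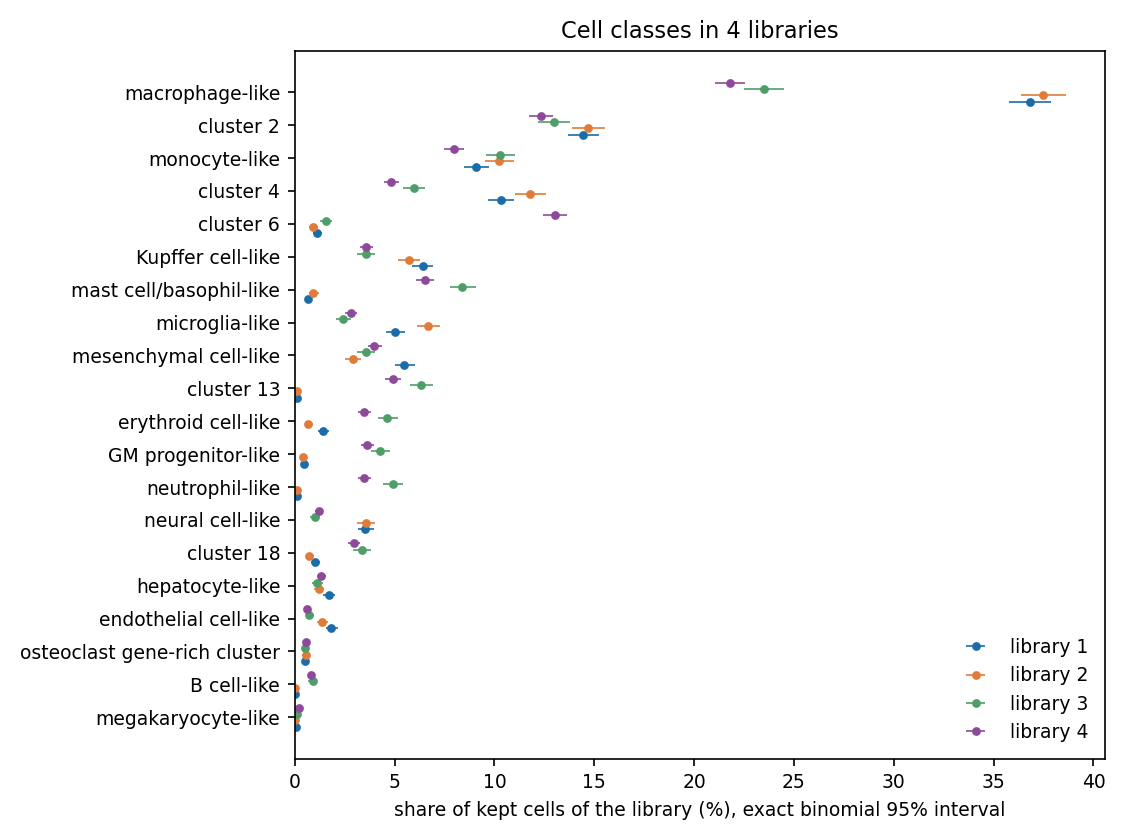
Share of the kept cells of each of the 4 libraries (horizontal axis, %) in each cell class (vertical axis). Points are libraries and lines exact binomial 95% intervals. Macrophage-like cells ranged from 21.8% to 37.5% of a library, and the osteoclast gene-rich cluster from 0.490% to 0.544%.

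The series title concerns osteoclast precursors, so their receptors were read in each class. Tnfrsf11a, which encodes RANK, the receptor for the osteoclast differentiation factor RANKL, was highest in a small osteoclast gene-rich cluster described below, at 72.7 CPM, the library-size-scaled count (exact Poisson 95% interval 64.6 to 81.4). Pooled over libraries, macrophage-like cells followed at 41.8 CPM (40.7 to 43.0), then cluster 4 at 38.5, microglia-like cells at 32.7, neural cell-like cells at 30.4 and Kupffer cell-like cells at 26.0. Because doublets were not excluded in the neural cell-like class, its value is not read as expression by neural cells. The order of these classes differed between libraries, with cluster 4 at 48.6 and macrophage-like cells at 45.1 CPM in library 3. Monocyte-like cells held 13.7 CPM (12.7 to 14.7) and granulocyte-monocyte progenitor-like cells 1.40 (0.977 to 1.93), which lay at the level of erythroid cells, 1.46 (1.07 to 1.95). Macrophage-like libraries ranged from 38.5 to 45.8 CPM and monocyte-like libraries from 10.1 to 17.7, a log2 ratio of 1.61 for the pooled classes. The monocyte-like value joined unlike clusters: cluster 5 held 26.0 CPM and cluster 12, led by Ly6c2 and Ear2, 3.65, so the log2 ratio was 0.69 against cluster 5 alone and 3.52 against cluster 12 alone, a split made after the data were seen. With a stricter cell filter it was 3.25, and with genes centred within libraries 3.24.

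Csf1r, the receptor for the macrophage growth factor CSF1, was highest in microglia-like cells, at 1878 CPM (1854 to 1902), against 1104 in macrophage-like, 802 in Kupffer cell-like, 451 in monocyte-like and 105 in progenitor-like cells. The fractalkine receptor Cx3cr1 followed the same order at the top, with 899 CPM in microglia-like and 525 in macrophage-like cells. These pooled values joined unlike libraries. In libraries 1 to 4 macrophage-like cells held 390, 389, 727 and 677 CPM of Cx3cr1, and microglia-like cells 694, 742, 1226 and 1155. Pooled, Cx3cr1 was lower in Kupffer cell-like (226), monocyte-like (116) and progenitor-like cells (19.5). In the osteoclast gene-rich cluster Csf1r (348 CPM) and Cx3cr1 (79.3 CPM) were both lower than in macrophage-like cells, although Tnfrsf11a was higher there. Neural cell-like cells also held Csf1r, at 810 CPM, and Cx3cr1, at 336 CPM, with the same limit.

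**Figure D2:**
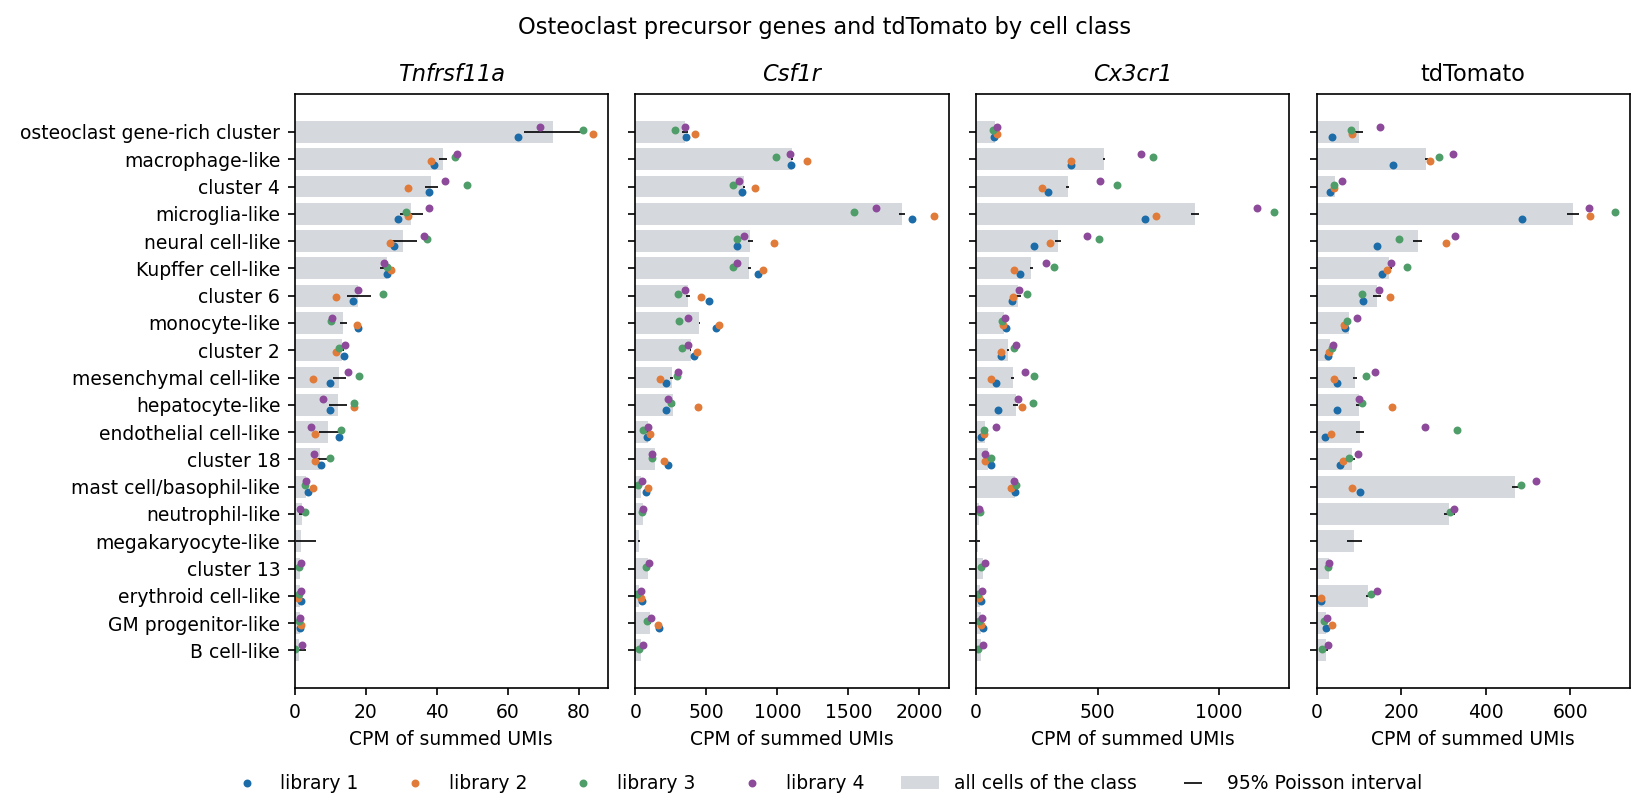
CPM of summed UMIs (horizontal axes, linear) of Tnfrsf11a, Csf1r, Cx3cr1 and tdTomato in each cell class (vertical axis). Grey bars are all cells of a class, black lines exact Poisson 95% intervals, and points the libraries with at least 30 cells of it. Tnfrsf11a reached 72.7 CPM in the osteoclast gene-rich cluster and 41.8 in macrophage-like cells, and Csf1r 1878 CPM in microglia-like cells.

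A cluster of 180 cells carried a broad set of osteoclast effector genes, those for bone resorption and cell fusion. It held 41, 38, 36 and 65 cells of libraries 1 to 4, 0.524% of all kept cells (0.450 to 0.606). Acp5, the tartrate-resistant acid phosphatase used as the classic osteoclast stain, stood at 1566 CPM (1527 to 1604), the collagen-cleaving protease gene Ctsk at 1414 (1378 to 1451) and the gelatinase gene Mmp9 at 1047 (1016 to 1079). The proton pump subunit Atp6v0d2 reached 292 CPM and the transcription factor Nfatc1, which drives osteoclast differentiation, 207. The fusion genes Dcstamp and Ocstamp reached 90.1 and 86.2 CPM, with Car2 at 195, Mmp14 at 158, Tcirg1 at 151, Src at 48.1, Ostm1 at 24.3 and Clcn7 at 16.5. In macrophage-like cells Acp5 stood at 22.7 CPM, Ctsk at 1.38, Mmp9 at 6.98 and Atp6v0d2 at 3.10. Tcirg1 stood at 54.3 CPM there, Ostm1 at 21.1, close to its level in the cluster, and Clcn7 also differed by less than 2-fold.

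Of the 15 effector genes, 10 were at least 4-fold higher in this cluster than in macrophage-like cells on the log2(CPM + 10) scale. Over the 14 effectors with enough UMIs the median log2 difference was 3.14, and it was above 0 in all 4 libraries. Set against the highest other class for each gene, with shallow cluster 6 left out, 8 of the 15 were over 2-fold higher here, counting Calcr, and 6 were lower. Car2 was higher in erythroid cells and Itgb3, at 5.89 CPM here, in megakaryocyte-like cells. Calcr, the calcitonin receptor gene, held a single UMI, or 0.246 CPM (0.00622 to 1.37). The cluster was picked after the data were seen, because it had the highest share of effector UMIs, so high effector levels in it follow in part from that choice. The effectors themselves took no part in the clustering.

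Several other gene groups were lower in the osteoclast gene-rich cluster than in macrophage-like cells, whereas the S phase list (0.44, from 0.32 to 0.59 over the libraries) and the G2 or M phase list (0.41, from 0.05 to 0.80) were higher and MHC class II stood at 0.05. The inflammatory mediators had a median log2 difference of -3.63 (-4.10 to -2.60), with 9 of 10 genes over 2-fold lower, among them Ccl4 (26.0 against 674 CPM) and Ccl2 (52.1 against 844). The efferocytosis and lysosome list stood at -2.53, with Gas6, a bridge between dying cells and phagocytes, at 10.3 against 681 CPM. Iron and haem handling stood at -1.34, with the iron exporter Slc40a1 at 4.17 against 221 CPM, and the immediate early genes at -2.00. Genes outside the lists that were higher included S100a6 (729 against 23.3 CPM), Traf1 (151 against 2.29) and Nrp2 (468 against 30.2). The precursor receptors and regulators had a median of -0.34, below 0 in all 4 libraries, with Trem2 (155 against 576) and Csf3r (1.96 against 19.2) lower. Of their other members, the transcription factor genes Spi1 (774 against 545) and Mitf (53.8 against 20.9) were higher, the signalling adaptors Fcer1g (1205 against 3958) and Tyrobp (1624 against 2518) lower, and Oscar, an osteoclast-associated receptor gene, stood at 4.42 against 0.0389. Itgam, Csf2ra and Traf6 (6.63 against 7.30) differed little.

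**Figure D3:**
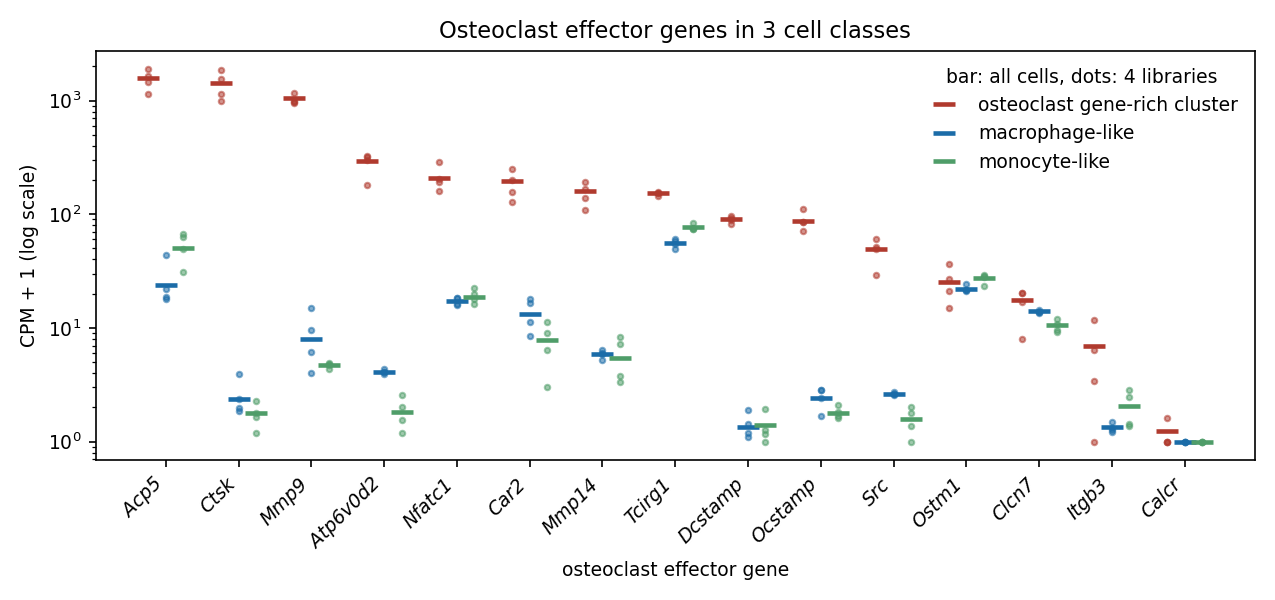
CPM + 1 (vertical axis, log scale) of the 15 osteoclast effector genes (horizontal axis) in the osteoclast gene-rich cluster, macrophage-like and monocyte-like cells. Bars are all cells of a class and dots the 4 libraries. Acp5 stood at 1566 CPM in the cluster and 22.7 CPM in macrophage-like cells.

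Cells holding UMIs of both Csf1r and Tnfrsf11a were more frequent among macrophage-like than monocyte-like cells. With each cell thinned to 2000 UMIs, 7.38% of 9644 macrophage-like cells held both (exact binomial 95% interval 6.87 to 7.92), from 6.53% to 8.42% over the libraries. The share was 6.12% in cluster 4, 5.52% in microglia-like and 3.89% in Kupffer cell-like cells, and 69 of 3130 monocyte-like cells held both. In the osteoclast gene-rich cluster 9 of 180 cells did, but thinned to 4000 UMIs its share was 22.5% (16.6 to 29.3) against 15.3% in macrophage-like cells, and unthinned 78.9%, so no order between these was read. Thinned to 2000 UMIs, no erythroid cell of 893 held both, which allows a share of up to 0.336% at that depth. No progenitor-like cell of 797 did either, which allows up to 0.376% at that depth. Median depths before thinning were 12500 UMIs in macrophage-like and 35718 in erythroid cells. Left out as too shallow were 332 macrophage-like, 23 monocyte-like and 12 erythroid cells. Without thinning the shares were 38.2%, 17.0% and 2.65% in macrophage-like, monocyte-like and erythroid cells, so the share of cells called positive was set largely by depth. The share expected if the genes were detected independently is not given, so these shares do not show a distinct subset of cells. The monocyte-like share joined clusters 5 and 12, which held 26.0 and 3.65 CPM of Tnfrsf11a.

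Macrophage-like cells were set against monocyte-like cells list by list. The efferocytosis and lysosome list was higher in macrophage-like cells, with a median log2 difference of 1.15 (0.83 to 1.38 over the libraries) and 7 of 13 genes over 2-fold higher. Its members Gas6 (681 against 77.1 CPM), Stab1, a scavenger receptor (760 against 92.9), Cd36 (147 against 15.3), Lgmn (2463 against 567), Ctsb (5617 against 1668) and Ctsd (2856 against 904) were higher, whereas Npc2 was not (895 against 1133). Iron and haem handling stood at 0.68, with Hmox1 (715 against 237), Slc40a1 (221 against 36.2), Ftl1, Fth1 and Trf all higher. Both medians depended on the monocyte-like cluster: efferocytosis stood at 0.57 and iron and haem handling at 0.20 against cluster 5 alone, and at 1.89 and 1.29 against cluster 12 alone. The inflammatory mediators stood at 0.77, led by Ccl7 (429 against 78.6), with Cxcl1 (30.6 against 4.48), Ccl12 (591 against 233) and Ccl2 (844 against 346) also over 2-fold higher, smaller differences for Ccl3, Ccl4 and Cxcl2, and Il1b lower (107 against 202). The median ranged from 0.25 to 1.41 over the libraries, whose cells of stress-led cluster 11 numbered 76, 81, 470 and 761. Without cluster 11, a choice made after the data were seen, it was 0.28, and against cluster 5 or cluster 12 alone 0.14 or 1.59.

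MHC class II genes, which present antigen, were lower in macrophage-like cells, with a median log2 difference of -2.31, and -1.48 in the library nearest 0, through Cd74 (80.7 against 563 CPM), H2-Aa (5.59 against 84.0), H2-Ab1 (6.56 against 72.3) and H2-Eb1 (2.94 against 48.9). With cluster 12 alone as the monocyte-like class it was -0.25. The S phase list stood at -0.22, with Rrm2 at 64.4 against 170 CPM and Mcm3, Mcm5 and Mcm6 within 2-fold. The G2 or M phase list stood at -0.47 (-0.68 to 0.02 over the libraries), with Top2a and Ube2c lower in every library and Cdk1 and Birc5 in 3. Both cell cycle lists had the other sign, 0.54 and 1.57, against cluster 5 alone. The remaining lists had smaller medians, some of which moved with the settings. Osteoclast precursor receptors and regulators stood at 0.23 (0.57 against cluster 12 alone), where Csf1r, Cx3cr1, Tnfrsf11a and Trem2 were over 2-fold higher and Csf3r and Csf2ra over 2-fold lower, with Itgam at 34.3 against 71.5 CPM. Mitf (20.9 against 9.09) and Fcer1g (3958 against 2832) were higher too, and Spi1 (545 against 617), Tyrobp, Traf6 and Oscar differed little. Secreted growth factors stood at 0.22 (0.86 with only genes of at least 50 CPM), with Igf1 at 283 against 38.1 CPM, Osm at 22.3 against 115, Sema4d at 17.6 against 34.0 and Tgfb1 at 356 against 339. The fetal programme stood at 0.19 (0.62 with that filter), with H19 at 64.4 against 17.7 CPM and Igf2bp1, Igf2bp3 and Hmga2 within 2-fold, and osteoclast effectors stood at 0.06. Immediate early genes stood at -0.03, with Jun higher (1116 against 623) and Dusp1 lower, whereas Fos was lower in 3 libraries and Junb in 2.

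Outside the lists, the genes with the largest differences included the lysosomal membrane gene Cd63 (983 against 129 CPM), Syngr1, Ltc4s, Gatm, Crybb1 and Serpinb6a, all higher in macrophage-like cells. Stfa1 (33.3 against 3716), the haemoglobin-binding protein gene Hp (9.62 against 889), S100a6, Mcemp1, Ifitm6, Stfa3, Ltb4r1, S100a11, Lgals3 (142 against 1703) and Glipr2 were lower. The same direction in all 4 libraries was a condition for listing these genes. Mcemp1, Hp and Ltb4r1 were among the top genes of cluster 12, so their differences may not hold for both monocyte-like clusters. Among 10000 random lists matched on expression, the medians of the MHC class II and G2 or M phase lists lay at percentiles 0 and 0.08, as a description of these cells. Those of efferocytosis and osteoclast effectors lay at 100 and 45.6.

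Macrophage-like cells differed more widely from granulocyte-monocyte progenitor-like cells, which carry Elane, Mpo and Ctsg. Of 1579 held-out genes compared, 130 were at least 4-fold higher and 31 at least 4-fold lower in macrophage-like cells, a count of sizes and not of tested changes. Among the highest were Lgmn (2463 against 56.9 CPM), the lipid carrier Apoe (24349 against 682), Gas6, Ccl12, Stab1, C3ar1, Ccl2, Ccl7, Cxcl2 and Hmox1. Among the lowest were Stfa1 (33.3 against 3078), Hp, Slpi, Cst7, Mgst1, BC100530, Phgdh, Gsr, Nrg1 and Rgcc. Pooled over libraries, precursor receptors and regulators stood at a median log2 difference of 1.21, efferocytosis at 3.30, inflammatory mediators at 2.51, immediate early genes at 1.94 and S phase genes at -0.76. Only libraries 3 and 4 held at least 100 progenitor-like cells, so these directions were read in 2 libraries. The pooled values join unlike libraries, since progenitor-like cells numbered 38, 30, 299 and 435 and macrophage-like cells 3079, 2648, 1644 and 2605 in libraries 1 to 4. Within libraries 3 and 4, inflammatory mediators stood at 3.06 to 3.23, efferocytosis at 3.33 to 3.34 and immediate early genes at 1.80 to 1.81, so these pooled values lay outside both.

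Microglia-like and Kupffer cell-like cells were also set against macrophage-like cells. In microglia-like cells Ldhb (375 against 32.6 CPM), F11r, Spint1, the fructose transporter gene Slc2a5 and Csf1 (98.3 against 6.81) were higher, and Ccl7 (36.4 against 429), Clec4a1, Clec10a and Folr2 lower. The precursor receptor list stood at 0.46 there and the inflammatory list at -0.59, although Ccl3 (1776 against 862) and Ccl4 (1703 against 674) were higher. Immediate early genes stood at -0.019 pooled but from -0.002 to 0.178 over the libraries, with the pooled sign in only 1 of 4. In Kupffer cell-like cells the iron and haem list was higher, at 0.72, with Spic, a transcription factor of iron-recycling macrophages, at 222 against 3.80 CPM. Il18bp, Vcam1 and Acp5 (217 against 22.7) were also higher. Inflammatory mediators stood at -0.95 there, with the list of immediate early and dissociation stress genes at -0.62, and precursor receptors and regulators at -0.41.

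The tdTomato reporter was highest in microglia-like cells, at 607 CPM (593 to 620.5), and this held in each library. Mast cell or basophil-like cells held 470 CPM pooled (462 to 478), but 101 and 83.4 in libraries 1 and 2, below macrophage-like cells there (180 and 268), and 484 and 519 in libraries 3 and 4. Neutrophil-like cells, almost all from libraries 3 and 4, held 315 and 326 CPM there, against 289 and 322 in macrophage-like cells. Pooled, macrophage-like cells held 260 CPM (180 to 322 over the libraries), neural cells 239 (142 to 329), Kupffer cell-like cells 172, the osteoclast gene-rich cluster 99.2 (37.3 to 151), monocyte-like cells 77.1, cluster 4 43.2 and cluster 2 32.7. Progenitor-like and B cell-like cells held 22.8 and 21.9 CPM. This pooled order did not hold in each library. Neural cells stood above macrophage-like cells in library 2 (305 against 268 CPM) and library 4 (329 against 322), and below them in libraries 1 and 3. Thinned to 2000 UMIs, 57.3% of microglia-like, 58.6% of mast cell or basophil-like, 29.3% of macrophage-like, 17.8% of osteoclast gene-rich and 3.11% of B cell-like cells held a tdTomato UMI, against 74.9%, 94.9%, 52.4%, 48.3% and 23.0% unthinned. No class is known to lack the reporter in every library, so no background level was set. The shares above were taken over all libraries together. Like mast cell or basophil-like cells, erythroid and endothelial cells split by library. Erythroid cells held 9.60 and 10.97 CPM in libraries 1 and 2, against 129.4 and 142 in libraries 3 and 4. Endothelial cells held 20.45 and 33.51 CPM in libraries 1 and 2, against 331.8 and 255.8 in libraries 3 and 4. The cause was not tested.

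In the GENCODE M21 annotation of mouse genome build GRCm38, the assembly also called mm10, the main genes are protein-coding. Tnfrsf11a (ENSMUSG00000026321) lies on chromosome 1 from 105780718 to 105847981, Csf1r (ENSMUSG00000024621) on chromosome 18 from 61100598 to 61132149, and Cx3cr1 (ENSMUSG00000052336) on chromosome 9 from 119901616 to 120069879. Acp5 (ENSMUSG00000001348) lies on chromosome 9 from 22126727 to 22135711, Ctsk (ENSMUSG00000028111) on chromosome 3 from 95499256 to 95509362, and Mmp9 (ENSMUSG00000017737) on chromosome 2 from 164940780 to 164955850.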

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

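The test of free RNA in neural cells, the high-scoring cells set beside them and the test of doublets in the osteoclast gene-rich cluster were chosen after results had been seen, and the reading of the doublet test in neural cells was changed after its result. Barcodes removed by the cell filter, which no comparison of cell classes uses, held a far larger share of globin UMIs than kept cells. The share was 33.7%, 27.3%, 29.8% and 20.5% of UMIs in removed barcodes of libraries 1 to 4, against 1.10%, 0.417%, 0.588% and 0.666% in kept cells.

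Neural cells, defined by Tubb3 and Stmn2, also held macrophage genes, with Csf1r at 810 CPM and Cx3cr1 at 336 CPM. Free RNA from macrophages as the whole source is argued against if barcodes of a library take up alike amounts, an assumption not tested. Neural cells held at least 7.09 times as many Csf1r UMIs per cell as erythroid cells in each library. They held only 1.45 to 6.16 times as many as hepatocyte-like and mesenchymal cells. For doublets of 2 cells, libraries 1 and 2 hold cells of both sexes. There 8.15% of Xist-positive neural cells also held a Y-linked UMI (exact binomial 95% interval 5.39 to 11.7). At that depth the share was 20.7% of simulated pairs, 15.8% of cells with the highest doublet scores and 3.29% of single macrophage-like cells. Each pair joined a macrophage-like cell to a random kept cell of the same library. The share was 8.88% of mesenchymal and 10.9% of hepatocyte-like cells. The reading fixed beforehand took a share below the pairs by more than both 95% intervals as excluding doublets, and this was met. That reading was too strong, because both cells of a pair were drawn without regard to embryo, while clumped cells of 1 embryo share a sex. The share of neural cells also lay above that of single cells. Doublets among part of these cells, or formed within 1 embryo, therefore cannot be told apart from cells expressing both sets of genes, and no biological explanation was tested.

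The osteoclast gene-rich cluster appeared in all 4 libraries at a similar share. Doublets of 2 cells of other classes are argued against by Acp5 and Ctsk, both at least 7.22-fold above the highest other class, since a doublet averages its cells. This leaves open doublets of an osteoclast gene-rich cell with another cell. Clustering that depended on the genes placed by the coin toss is argued against as well. In 5 of 5 other gene splits 1 cluster held from 80.6% to 97.2% of the same cells. These cells made up from 74.6% to 94.8% of the matching cluster. All cell type markers were used in every split, so dependence on those genes, S100a4 of this cluster among them, was not tested. Cells of the osteoclast lineage remain as a hypothesis, found and tested on the same data.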

How the results depend on the processing

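Alternatives without the highest doublet scores, with single monocyte-like clusters, or without cluster 11 were chosen after seeing the data; the others were planned. The osteoclast gene-rich cluster held 0.480% to 0.579% of cells in 11 alternatives, and 10 effectors were at least 4-fold higher in each of 14. The log2 ratio of Tnfrsf11a between macrophage-like and monocyte-like cells stayed above 0 in all 15 but moved from 1.61 to 2.01 with doublets kept, 3.25 with the stricter cell filter, 2.07 with all genes used in clustering, 3.24 with genes centred within libraries and 1.38 as the mean of each cell's CPM. It was 0.69 with cluster 5 and 3.52 with cluster 12 alone as monocyte-like, and from 1.41 to 1.79 leaving out each library. At resolution 0.3 no cluster was mostly monocyte-like, so no value was had. Which cells were called monocyte-like differed between settings; beyond the 2 single clusters the cause was not tested. Cells with both Csf1r and Tnfrsf11a made up 38.2% with no thinning, 3.05% at 1000 and 15.3% at 4000 UMIs, by construction of the depth, and tdTomato-positive macrophage-like cells 29.3% when thinned. Of 143 alternative list medians, 7 had the other sign. Against cluster 5 alone, S phase stood at 0.54, G2 or M phase at 1.57 and osteoclast effectors at -0.023. Against cluster 12 alone, immediate early genes stood at 0.36. With only genes of at least 50 CPM, precursor receptors stood at -0.076, effectors, of which only Tcirg1 was left, at -0.41 and immediate early genes at 0.034, since fewer genes enter. For the others the cause was not tested. No paired analysis was possible because the sample groups could not be tied to libraries, and the planned edgeR tests and their alternatives were not run for the same reason. That reason covers comparisons of sample groups only. Macrophage-like, monocyte-like and osteoclast gene-rich cells occurred in every library, so their differences could be paired within libraries. Those differences are given as ranges, and a paired test of them was not run.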

Other observations

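The test below of the nearest class, and both tests of the library differences, were set before their results were seen. Beyond the classes compared above, cluster 18 held MHC class II genes, with Tnfrsf11a at 7.14 CPM and tdTomato at 83.6 CPM. Mast cell or basophil-like cells held Cx3cr1 at 158 CPM but Tnfrsf11a at only 3.07 CPM. Within the monocyte-like class, cluster 5 held Csf1r at 744 CPM and cluster 12 at 211 CPM, and Cx3cr1 stood at 226 and 26.0 CPM. Held-out genes of the osteoclast gene-rich cluster that stood above every other class of at least 100 cells except shallow cluster 6 included Nrp2 (468 against 170 CPM in endothelial cells) and Traf1 (151 against 51.3 in cluster 18), chosen after their values were seen.

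The libraries split on genes of sex and on cell classes. Xist stood at 491, 473, 0.189 and 0.0967 CPM in libraries 1 to 4, and the sum of 4 Y-linked genes at 41.0, 40.5, 116 and 114 CPM. Mast cell or basophil-like cells made up 0.658%, 0.934%, 8.39% and 6.51%, neutrophil-like cells 0.0837%, 0.0991%, 4.90% and 3.48%, B cell-like cells 0 (up to 0.0359%), 0 (up to 0.0425%), 0.886% and 0.828%, and macrophage-like cells 36.8%, 37.5%, 23.5% and 21.8%. Every library held hepatocyte-like cells (1.70%, 1.19%, 1.11% and 1.33%), microglia-like cells (5.01%, 6.67%, 2.43% and 2.81%) and neural cells (3.54%, 3.54%, 0.986% and 1.20%). For mast cell or basophil-like cells, a cluster that follows the library rather than the cell type is argued against. With genes centred within libraries, their lowest share of libraries 3 and 4 was still 8.22 times the highest of libraries 1 and 2. The cell filter is argued against for these cells too. Among all barcodes, the same ratio for barcodes with at least 3 Cpa3 UMIs was 10.3. Other classes and clusters that differed between libraries, such as clusters 6, 11 and 13, were not tested in this way. Embryos, sex, preparation, and driver line together with the day of 4-hydroxytamoxifen stay open and untested, because no library is tied to a sample. No group was inferred from these values.

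One hypothesis was that the osteoclast gene-rich cluster lies nearest to the monocyte-like class rather than the macrophage-like class. Over genes open to clustering, Pearson's r across genes, which are not independent replicates, was higher with the monocyte-like class in 0 of 4 libraries. It was 0.821, 0.830, 0.822 and 0.830 there, against 0.850, 0.850, 0.833 and 0.835 with the macrophage-like class. The higher r with the monocyte-like class that the hypothesis called for was therefore not seen for the joined class, though the values lay close in libraries 3 and 4. Monocyte-like clusters 5 and 12 were not tried separately. The highest r was with unnamed cluster 2, at 0.895, 0.901, 0.888 and 0.897 in libraries 1 to 4, followed by cluster 4 in libraries 1 and 2 and by cluster 13 in libraries 3 and 4. Of the named classes, granulocyte-monocyte progenitor-like cells had the highest r in every library (0.873, 0.865, 0.863 and 0.873), and Kupffer cell-like cells also lay above macrophage-like cells (0.850, 0.850, 0.833 and 0.835) in each. Classes of other lineages lay above macrophage-like cells too. B cell-like cells did so in libraries 3 and 4 (0.840 and 0.864). Hepatocyte-like cells did so in libraries 1 and 4 (0.859 and 0.848), lay close in library 2 (0.850) and below in library 3 (0.831). This r did not separate lineages, so it cannot decide between a monocyte-like and a macrophage-like origin. A likeness of profiles does not show descent.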
